A study of Homo sapiens with 5 samples.

How the data were processed

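Human U373MG cells, an astrocytoma line, were infected with an adenovirus carrying p53 (Ad-p53) and harvested at 0, 6, 12, 24 and 48 h. RNA of each time point was labelled with Cy3 and hybridised to a cDNA array against Cy5-labelled RNA of cells infected with an adenovirus carrying LacZ (Ad-LacZ), which encodes a bacterial β-galactosidase. The reference was mixed RNA of Ad-LacZ cells, per the series design text, and it was taken as 1 common mixture for all 5 arrays. Its make-up in time points is not given in the sources used here. There was 1 array per time point, no dye swap and no replicate culture. The labels give 2 multiplicities of infection, 20 in the series design and 8 in the treatment protocol, and the data do not settle which was used. Dishes held 2000000 plated cells and 2.5 µg of mRNA was labelled, per the labels' protocols.

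The deposited sample files hold raw spot intensity on a linear scale, in duplicate for each channel, per the file headers and the accompanying readme: columns 1 and 2 for Cy3 and columns 3 and 4 for Cy5. The scanner, software and background method are not given in the sources used here. The values are never below 0 and many are exactly 0, so they were treated as already corrected for background and no further correction was applied. What the duplicates are, beyond a duplicated analysis, is not given in the sources used here. Of 36864 spots, 23040 carried values on all 5 arrays. The labels give 23504 analysed spots and the readme 23070. The spots fall into 5 runs of 4608 with separate signal levels, called slides here. That each run is a separate slide was inferred from these levels. The authors also deposited a matrix of log2 ratios, Ad-p53 over Ad-LacZ per the readme. The offset between these values and the log2 ratio of the summed duplicates was taken over spots above 30000 units in all 4 measurements. It varied least on slides 3 to 5. There the 5th to 95th percentile ran for example from 1.1 to 1.15 on slide 3 at 0 h and from 0.489 to 0.626 on slide 4 at 48 h. It varied more on slide 2 (1.15 to 4.21 at 12 h) and on most arrays of slide 1 (3.1 to 5.26 at 6 h), but not on slide 1 at 24 h (1.72 to 1.87). How the authors scaled and filtered them is not given in the sources used here. The column medians of the matrix lay between -0.109 and 0.0945. Across spots with both values, bright or dim, the loess ratios described below correlated with the matrix with r between 0.531 and 0.733. Authors' values beyond 10 in size were left out of that correlation. Of 4125 spots with no signal on any array, 1412 have an authors' log2 ratio on all 5 arrays, and 41 to 410 values per array lie beyond 10 in size. The matrix was therefore used as an alternative only.

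Both duplicates were averaged per channel and spots with 0 in either channel were left out of that array. The log2 ratio of Cy3 over Cy5 was normalised within each slide and array by loess on mean log2 intensity (limma 3.58.1 in R 4.3.3, span 0.3, 4 iterations). Loess was first planned per array and was run per slide because the levels differ between slides. Median centring was likewise run per slide. A dim-spot filter at the 10th percentile of each channel had been fixed before the data were examined. That percentile is 0 here, so the percentile was taken over signals above 0. A gene was left out of a comparison when both channels of both arrays lay under it. Spots above 30000 units in all 4 measurements numbered 2606 to 4534 per array. Before normalization, their duplicate log2 ratios correlated across spots of all slides with r between 0.932 and 0.958. The difference of the duplicates had an SD between 0.311 and 0.441. Levels that differ between slides are shared by both duplicates and can raise this r, and dimmer spots are not covered. The duplicates share 1 RNA sample, so the SD of 2 duplicates given with a value does not cover the variation between cultures. It covers only the part of measurement error in which the duplicates differ, and not errors they share, such as those of a probe or an array. Precision was limited by the number of arrays.

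Probes were named through the platform annotation, with symbols updated by Entrez ID through the RefSeq table of GRCh38.p14. Of the spots with values, 13239 had 1 symbol, 82 had several and were not named, and 9719 were not listed in the annotation. The Entrez ID of 13202 probes matched the RefSeq table and that of 119 did not. This left 9835 genes, of which 2541 had more than 1 probe. The probe with the highest mean signal over arrays and channels represented the gene. No coordinates are given because the array names no genome build.

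The main measure was the change of the log2 ratio from the 0 h array, which removes the reference and any constant dye effect of a spot. All 4 later time points share the 0 h array, so errors of that array enter each of them. Genes at least 2-fold from 0 h were counted with no test. A monotone course was tested with limma (lmFit and eBayes with an intensity trend, two-sided) on the rank of the 5 time points, with 3 residual degrees of freedom per gene and Benjamini-Hochberg adjustment at 0.05. Departure from a straight line was the only error this design provides, and the p-values do not cover differences between cultures. The 19 lists, of which 4 hold markers of other cell types, were fixed before the data were examined. They cover 4 groups of p53 targets (arrest and repair, cell death, feedback, metabolism and secretion), mitosis, DNA replication, interferon-stimulated, NF-kB, integrated and ER stress, heat shock, extracellular matrix, cholesterol synthesis, respiratory chain, ribosomal protein, and astrocyte and glioma genes. The marker lists are for epithelial cells, neurons, leukocytes and endothelial cells. Pooling the 4 p53 lists was not part of that plan. For each list the median change was set against 10000 random lists of the same size matched on mean intensity. Counts past the trend test are given over all genes and adjusted over the list alone.

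The genes named below follow a rule fixed before the data were examined. It takes 1 gene that is not reported here, then up to 15 genes per direction with the largest mean of the 24 and 48 h changes among those past the trend test, filled with genes at least 2-fold at both times. It adds the 5 highest and 5 lowest changes at 6 and at 12 h, and from each list the 4 members with the largest mean change at 24 and 48 h. Other members are named where they passed the trend test adjusted over their list alone, or because another probe of a named gene was compared.

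The trend step was tested on simulated data for 6510 genes, with normal noise scaled to the residual SD of genes of like intensity. It recovered 39 of 65 genes with a slope of 1 log2 unit per time point, 8 of 69 with 0.5 and 0 of 66 with 0.25, with 5 false calls. The ratio step was tested on 14866 simulated spots of 2 arrays, with noise of SD 0.2 log2 units added. It returned 200 known ratios, drawn among brighter spots only, with a median absolute error of 0.194 log2 units. That error mirrors the noise put in, which was below the duplicate SD of 0.311 to 0.441 in the data. The test checks the calculation and not the accuracy on these arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

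The alternatives fixed in advance were median centring, the authors' matrix, an offset of 50 in both channels, no dim filter, a filter at the median intensity, the mean over probes, a 3-fold threshold, the ratio to the mixture without subtracting 0 h, other time scales, no intensity trend in the variance, and each array left out of the trend. Chosen after seeing the data were a second loess along the slide, signals floored at the 10th percentile with no spot left out for a 0, a 2-fold change in both duplicates, random lists matched on the slide, and slides 3 to 5 only.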

Results

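The series follows U373MG cells, a human astrocytoma line, after infection with an adenovirus that carries p53. RNA was collected at 0, 6, 12, 24 and 48 h, with 1 array per time point, and compared on each array with mixed RNA of cells infected with a LacZ virus. The series title states the aim as profiling genes regulated by p53. Both channels gave a signal for 13853, 13154, 13651, 15453 and 14607 spots from 0 to 48 h, which is 57.1 to 67.1% of the spots, and a ratio was obtained for 7983, 7750, 8001, 8634 and 8195 genes. Signal levels differed between arrays within slides 1 and 2. The 90th percentile of the Cy3 signal of slide 1 was 308590 at 0 h, 27891 at 6 h, 10004 at 12 h, 125351 at 24 h and 383418 at 48 h. There were no replicate cultures and no LacZ sample matched in time, so no difference below has a replicate check, and effects of p53 and of time after infection are not separated. All changes share the 0 h array, and for that reason no correlation between time points is given. CDKN1A, the classical p53 target that encodes the cell cycle inhibitor p21, is not analysed here, since no probe carries it as its single symbol.

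**Figure D1:**
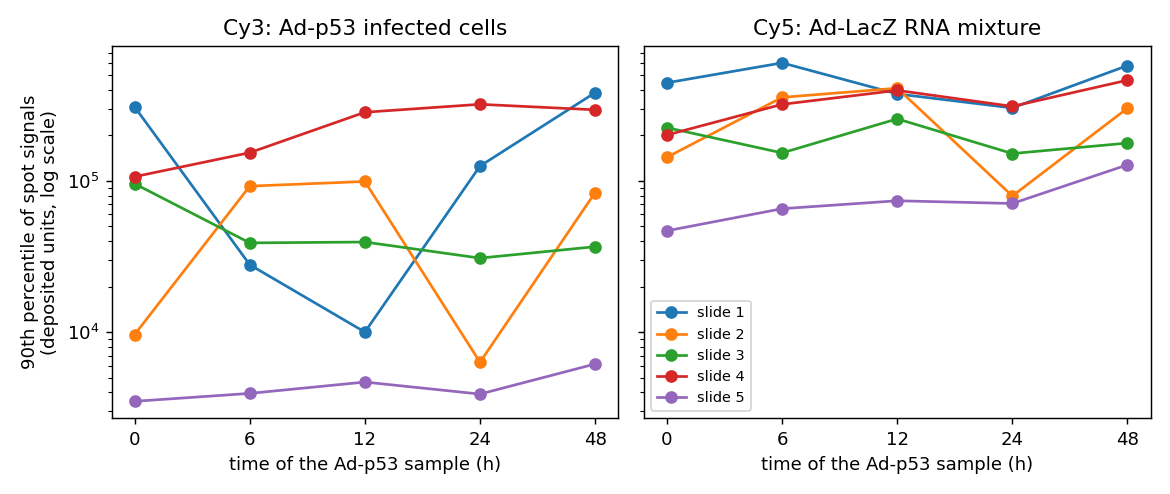
The 90th percentile of the deposited spot signals (log scale) is plotted against the time of the Ad-p53 sample (h) for each of the 5 slides, with Cy3 on the left and Cy5 on the right. Cy3 of slide 1 was 308590 at 0 h and 10004 at 12 h, and Cy3 of slide 2 was 9636 at 0 h and 99123 at 12 h.

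The trend across the 5 time points asks which genes went steadily up or down after Ad-p53 infection. Among the 8 genes that rose were PMEPA1, an inhibitor of TGF-beta signalling, CNNM4, a magnesium transporter, FHL2, a LIM-domain transcriptional co-regulator, and TRIAP1, a small p53-induced survival protein. PMEPA1 was 13.2-fold above 0 h at 24 h and 24.9-fold at 48 h, with log2 changes of 3.73 ± 0.19 and 4.64 ± 0.09 (SD of 2 duplicate measurements of the same sample). At 48 h CNNM4 was 21.5-fold, FHL2 14.5-fold, IER5 13-fold, the ephrin receptor kinase EPHB4 11.7-fold, the p38-activating kinase MAP2K3 9.19-fold, TRIAP1 8.95-fold and FAM83G 6.45-fold above 0 h. The 8 genes that fell were led by CNR1, the cannabinoid receptor of the brain, with log2 changes of -4.32 ± 0.28 at 24 h and -5.98 ± 0.28 at 48 h. At 48 h the collagen receptor kinase DDR2 was 44.3-fold, IQGAP3 37.6-fold, delta-catenin (CTNND2) 33.3-fold, the heparan sulfatase SULF1 18.5-fold, the ADP-ribosyltransferase PARP14 14.1-fold, the Rac regulator CHN1 13.5-fold and the microtubule destabiliser STMN1 12.7-fold below 0 h.

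These 16 genes passed limma's trend test with Benjamini-Hochberg adjustment, of 6510 tested. CNR1 had a slope of -1.52 ± 0.09 (SE) log2 units per time point and an adjusted p of 0.00341, and the other adjusted p-values lay between 0.0303 and 0.0493. An unadjusted p under 0.05 was reached by 786 genes, 425 upward and 361 downward, against 325.5 expected by chance. Both duplicates gave a signal on the 0, 24 and 48 h arrays for 15 of the 16, all but IQGAP3. The duplicate SD at 48 h was 1.75 log2 units for DDR2 and 1.20 for CTNND2. Other probes of PMEPA1, FHL2 and SULF1 gave log2 changes of 4.21, 3.31 and -3.52 at 48 h. A second probe of IQGAP3 gave 1.05 at 12 h, -2.95 at 24 h and -1.67 at 48 h. One of DDR2 gave 1.73 at 6 h, -3.08 at 12 h and -1.17 at 24 h. Against the mixture itself, 15 of the 16 lay at 0 h on the side opposite to their slope, as for PMEPA1 with a log2 ratio of -1.81 at 0 h and 2.83 at 48 h. Without the 0, 6, 12, 24 or 48 h array, 0, 2, 1, 0 and 0 genes passed, with 750, 707, 755, 658 and 751 at an unadjusted p under 0.05. Each of these fits has 1 residual degree of freedom fewer, so loss of power and dependence on an array are not told apart. All 16 genes kept their sign in each. The count was also 0 with median centring in place of loess and 74 with the authors' matrix.

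**Figure D2:**
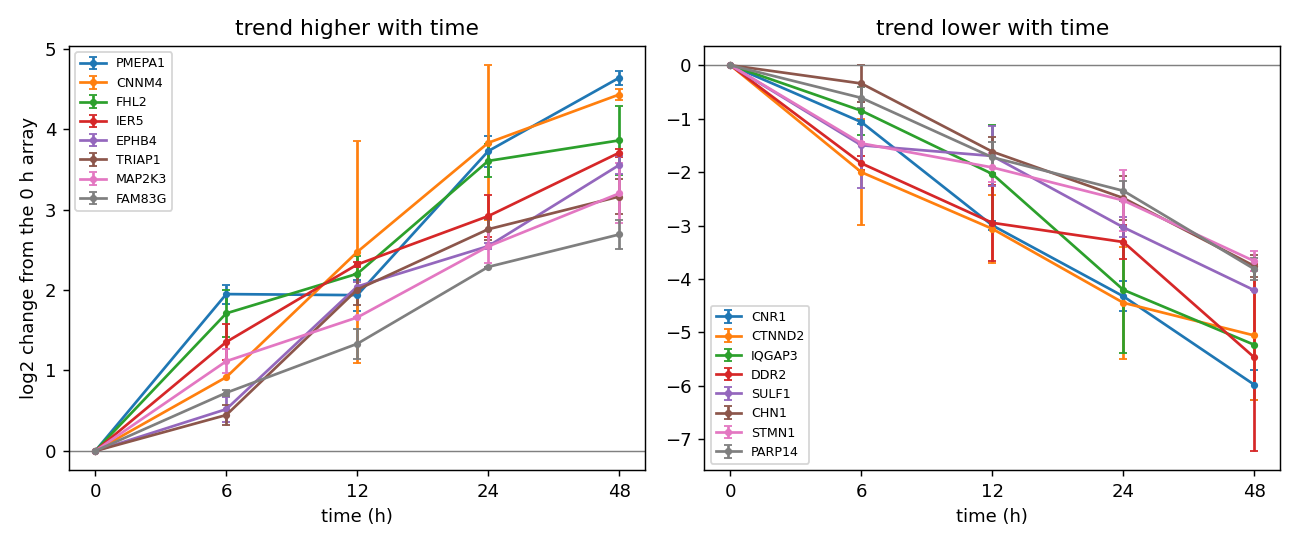
The log2 change from the 0 h array is plotted against time (h) for the 8 genes that rose (left) and the 8 that fell (right) in the trend test. Points are single arrays, and bars are the SD of 2 duplicate measurements, missing where a duplicate had no signal; PMEPA1 reached 4.64 and CNR1 -5.98 at 48 h.

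Known p53 target genes were higher at 48 h than at 0 h. GADD45A, a DNA damage-induced growth arrest gene, was 12.1-fold above 0 h at 48 h (log2 3.59 ± 0.13), the secreted stress factor GDF15 9.74-fold (3.28 ± 0.23), and the repair gene DDB2 6.85-fold (2.78 ± 0.52). Among the cell death genes, the netrin receptor UNC5B was 18.1-fold, CYFIP2 8.46-fold, IGFBP3, which binds insulin-like growth factors, 7.1-fold and the Akt inhibitor PHLDA3 7.02-fold above 0 h. MDM2, the ubiquitin ligase that degrades p53, was 2.77-fold (1.47 ± 0.07) and the phosphatase PPM1D 2.54-fold above 0 h. The chemokine CX3CL1 was 7.6-fold (2.93 ± 0.30), ALDH4A1 7.48-fold, SLC12A4 9.24-fold and the cytochrome oxidase assembly gene SCO2 3.32-fold above 0 h. NINJ1 was 26-fold and SFN (14-3-3 sigma) 19.3-fold above 0 h. For NINJ1, SFN, CYFIP2 and SLC12A4 a duplicate without signal on the 0 or the 48 h array leaves no duplicate SD, and that of PPM1D was 0.90 log2 units. The 4 p53 lists hold 103 genes, of which 60 had a probe with a single symbol. BAX, FAS and TNFRSF10B were among the genes without such a probe. Of 51 measured targets, 27 were at least 2-fold higher at 48 h. At least 2-fold lower were 4, among them TOB1 (log2 -1.12 ± 0.03).

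The median log2 change of the pooled targets was 0.11 at 6 h, 0.57 at 12 h, 0.47 at 24 h and 1.22 at 48 h. At 48 h all 10000 intensity-matched random lists had a lower median, at 24 h 9996, at 12 h 9998 and at 6 h 6870. At 48 h the median was 1.65 for arrest and repair (7 of 13 at least 2-fold higher), 1.23 for cell death (9 of 16), 1.14 for feedback (3 of 6) and 0.93 for metabolism and secretion (8 of 16). These lay above 10000, 9999, 9944 and 9988 random lists. Against the Ad-LacZ mixture the pooled median at 48 h was 1.13. In the trend test 1 of the 43 pooled targets tested, TRIAP1, passed over all genes, and 9 did adjusted over the list alone, all upward. Adjusted over the list alone for each separate list, 6 arrest and repair genes passed upward and 1, TOB1, downward, with 0 over all genes. The 6 were NINJ1, GADD45A, GDF15, DDB2, GPX1 and SESN2. Adjusted over the list alone, 4 cell death genes passed (PHLDA3, IGFBP3, AIFM2 and EI24, with 0 over all genes), 1 metabolism and secretion gene (CX3CL1, with 0 over all genes) and 1 feedback gene (TRIAP1, which also passed over all genes). Other probes of CX3CL1 and IGFBP3 gave 3.13 and 2.61 at 48 h. Probes of other targets disagreed: a second CYFIP2 probe gave -0.97 at 24 h and 0.73 at 48 h, a second SLC12A4 probe gave -1.35 at 48 h, and the 2 probes of cyclin G1 (CCNG1) gave -1.68 and 0.12 at 24 h.

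**Figure D3:**
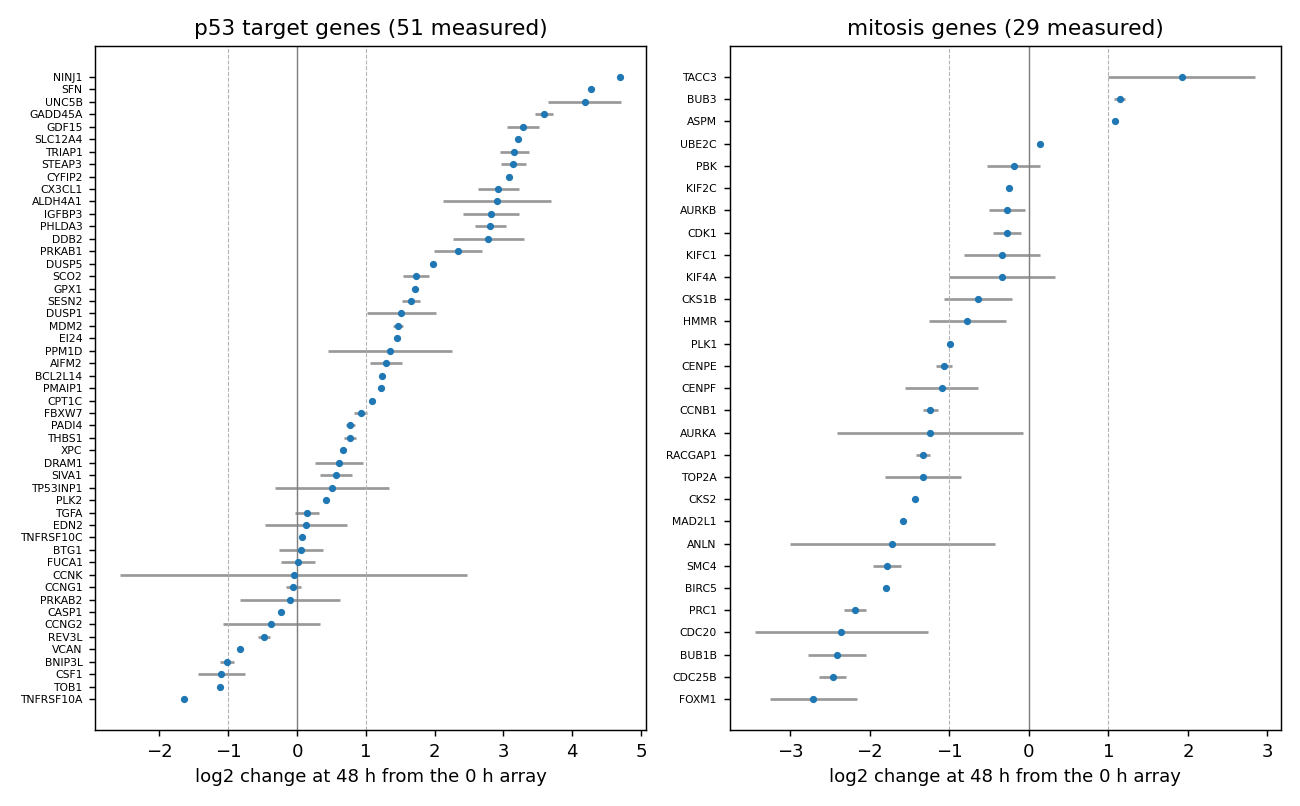
Each point is the log2 change at 48 h from the 0 h array of 1 gene, for 51 measured p53 targets (left) and 29 measured mitosis genes (right); bars are the SD of 2 duplicate measurements, missing where a duplicate had no signal, and dashed lines mark 2-fold. At least 2-fold higher were 27 of the p53 targets and 3 of the mitosis genes, and at least 2-fold lower were 4 and 16.

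Mitosis genes were lower from 12 h on. BUB1B, a spindle checkpoint kinase, was 16.1-fold below 0 h at 24 h (log2 -4.00 ± 0.18) and 5.32-fold at 48 h, the phosphatase CDC25B 8.89-fold and 5.53-fold, and CDC20, an activator of the anaphase-promoting complex, 7.78-fold and 5.13-fold. The cytokinesis gene ANLN was 16.3-fold and 3.28-fold below 0 h, with a duplicate SD of 1.29 log2 units at both times, and that SD was 1.06 for CDC25B at 24 h and 1.09 for CDC20 at 48 h. FOXM1, a transcription factor for mitosis genes, was 6.54-fold below 0 h at 48 h. Of the measured members, 5 of 41 were at least 2-fold lower at 6 h, 21 of 41 at 12 h, 24 of 38 at 24 h and 16 of 29 at 48 h, while 6, 2, 0 and 3 were at least 2-fold higher. The 3 at 48 h were TACC3, BUB3 and ASPM, chosen after their values were seen.

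The median log2 change of the mitosis genes was -0.22 at 6 h, -1.11 at 12 h, -1.44 at 24 h and -1.10 at 48 h. The mitosis median at 48 h rests on the 29 genes with a signal, and became -0.66 with signals floored (42 genes) and -1.90 with the authors' matrix (17 genes). At 12, 24 and 48 h 0 of 10000 random lists had a lower median, and at 6 h 390 had. In the trend test 0 of 29 passed over all genes and 7 passed downward adjusted over the list alone: PRC1, FOXM1, CDC25B, CDC20, BIRC5, CCNB1 and BUB1B. A second CDC20 probe gave -0.27 at 24 h and -1.04 at 48 h. Against the Ad-LacZ mixture the medians were 0.07, -0.77, -0.96 and -0.74, and on the 0 h array the list stood at 0.24, above the random range of -0.32 to 0.20.

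For the DNA replication genes the median log2 change from 0 h was 0.02 at 6 h, -0.03 at 12 h, -0.39 at 24 h and 0.03 at 48 h, and 118 of 10000 random lists had a lower median at 24 h. Against the Ad-LacZ mixture the medians at 6, 12 and 24 h were -0.41, -0.36 and -0.47, at percentiles 0.09, 0.81 and 0.17, and that at 48 h was -0.11, within the random range (percentile 28.1). The 0 h array itself stood at -0.37 (percentile 1.19). Geminin (GMNN), an inhibitor of replication licensing, was 6.65-fold above 0 h at 48 h, and DUT, which removes dUTP, was 2.62-fold below. The helicase subunits MCM3 and MCM6 were 3.86-fold (no duplicate SD) and 3.28-fold below 0 h at 48 h, but a second MCM6 probe gave a log2 change of 0.15. Over all genes 0 of 27 passed the trend test, and adjusted over the list alone GMNN passed upward and DUT downward.

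**Figure D4:**
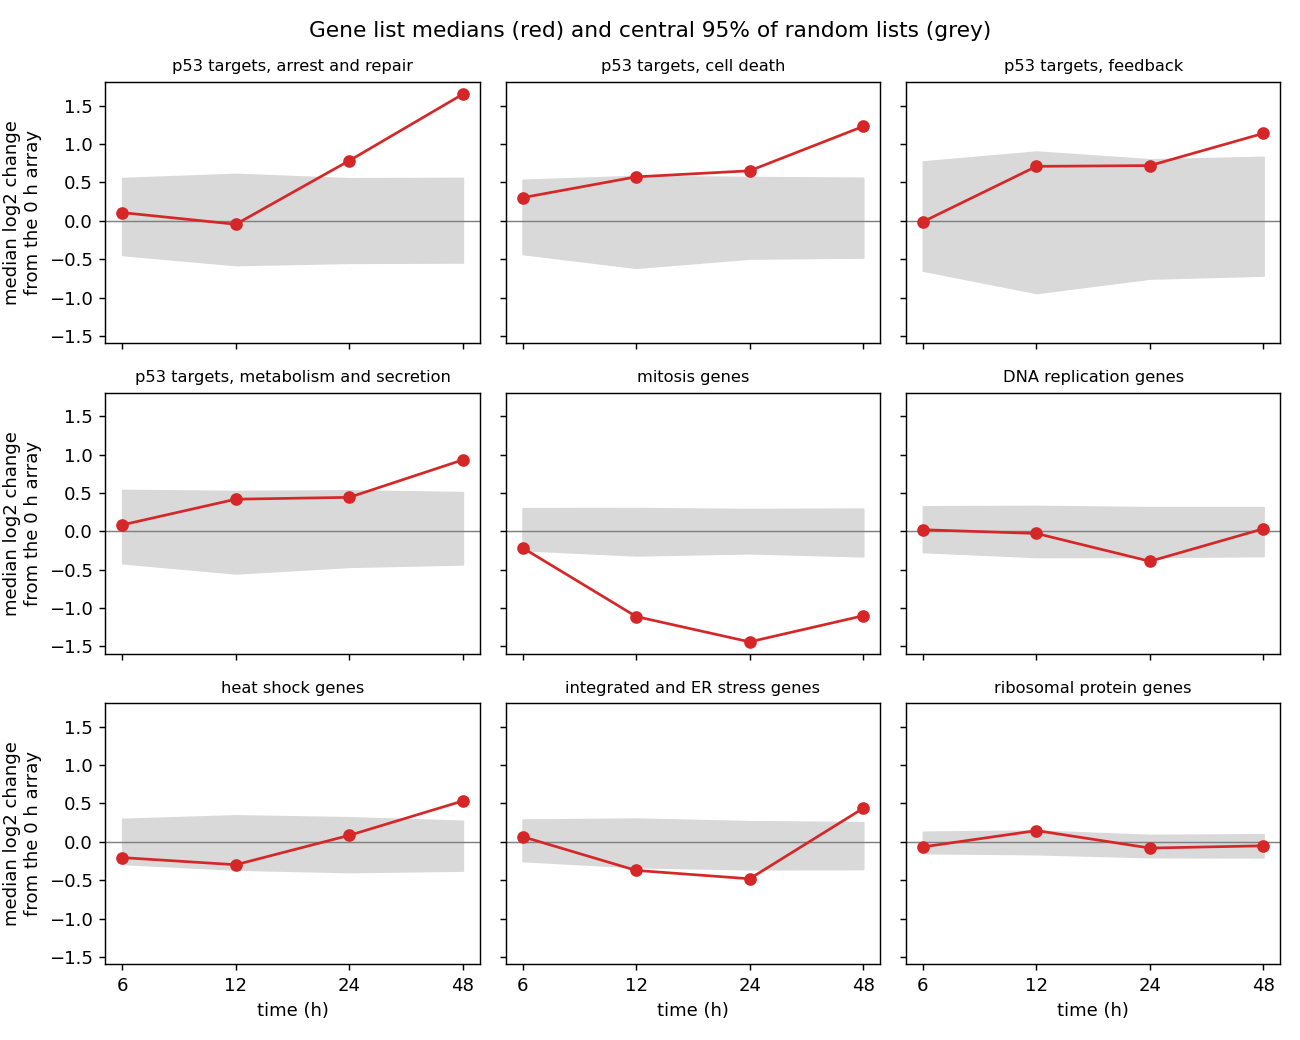
The median log2 change from the 0 h array (red) is plotted against time (h) for 9 gene lists, with the central 95% of 10000 random lists of matched size and intensity (grey). The p53 target lists end between 0.93 and 1.65 at 48 h, above the grey range, and the mitosis genes lie below it at 12, 24 and 48 h, at -1.44 at 24 h.

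Of the other lists, the heat shock genes were higher at 48 h. The co-chaperone BAG3 was 4.25-fold above 0 h at 48 h (log2 2.09 ± 0.03), the small heat shock proteins HSPB1 and CRYAB 4.21-fold (2.07 ± 0.14) and 3.97-fold (1.99 ± 0.24), and their regulator HSF1 4.99-fold. The list median was -0.21 at 6 h, -0.30 at 12 h, 0.09 at 24 h and 0.53 at 48 h, the last above 9992 of 10000 random lists. Against the mixture it was -0.29 at 6 h, -0.41 at 24 h and 0.29 at 48 h (percentiles 2.17, 0.7 and 99.1). Adjusted over the list alone BAG3, HSPB1 and CRYAB passed the trend test upward, with 0 of 17 over all genes. Second probes of HSPB1, CRYAB and HSF1 gave 2.76, 1.47 and 2.2 at 48 h. Against the mixture BAG3, HSPB1 and CRYAB stood at 2.09, 1.56 and 3.01 at 48 h. HSF1 stood at -2.25 on the 0 h array and at 0.07 at 48 h, so it did not differ from the mixture then.

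Integrated and ER stress genes were lower at 12 and 24 h and higher at 48 h than on the 0 h array, but of these only the value at 12 h lay outside the random range against the mixture. The transcription factor ATF3 was 3.73-fold above 0 h at 48 h, whereas DDIT4, an inhibitor of mTORC1, was 2.94-fold, SEL1L, of ER-associated degradation, 3.4-fold and the serine synthesis enzyme PHGDH 4.43-fold below 0 h at 24 h. The list median was 0.07, -0.37, -0.48 and 0.44 from 6 to 48 h, with 6461, 128, 33 and 9971 of 10000 random lists below it, and at 12 h the percentile was 4.69 when random lists were matched on the slide. Against the mixture the medians at 12, 24 and 48 h were -0.29, -0.11 and 0.15 (percentiles 1.14, 29.8 and 93.6), and the 0 h array stood at -0.28 (percentile 3.13). The trend test passed 0 of 21, over all genes and adjusted over the list alone.

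Interferon-stimulated genes as a list stayed within the random range, with medians of -0.30, -0.10, 0.04 and -0.34. OAS1, which senses double-stranded RNA, was 8.92-fold above 0 h at 24 h and 1.42-fold at 48 h. At 48 h IRF1 was 3.92-fold and the peptide transporter TAP1 3.72-fold above, and IFITM1 5.91-fold below 0 h. The NF-kB genes had medians of 0.16, -0.30, 0.20 and 0.04, within the random range, and 0.41 against the mixture at 12 h, at the edge of the random range. The cytokine LIF was 27.3-fold above 0 h at 48 h and 63-fold at 6 h, with a duplicate SD of 1.05 log2 units at 6 h. At 48 h the urokinase gene PLAU was 4.19-fold above, and the mitochondrial dismutase SOD2 and the adhesion molecule VCAM1 9.25-fold and 3.37-fold below. Against the mixture LIF stood at -3.80 on the 0 h array, 2.18 at 6 h and 0.97 at 48 h. PLAU stood at -2.10 on the 0 h array and at -0.04 at 48 h. The duplicate SD of VCAM1 at 48 h, 1.84 log2 units, exceeds its log2 change of -1.75, and OAS1 and SOD2 have no duplicate SD, since a duplicate lacked signal on one of the arrays compared. The trend test passed 0 of 18 interferon genes either way, and 0 of 14 NF-kB genes over all genes but SOD2 and CD83 downward adjusted over the list alone.

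Extracellular matrix genes had medians of -0.01, 0.11, 0.14 and -0.01, within the random range, but stood at -0.39 against the mixture at 6 h (percentile 0.08). The matricellular gene CCN1 was 15.4-fold above 0 h at 48 h (log2 3.95 ± 0.28), type VII collagen (COL7A1) 14.5-fold, with a duplicate SD of 1.42 log2 units, and the collagenase MMP1 3.75-fold. Against the mixture CCN1 stood at -3.37 on the 0 h array and 0.57 at 48 h, and COL7A1 at -1.73 and 2.13. LOXL1, a collagen and elastin cross-linking enzyme, was 9.19-fold above 0 h at 24 h, with a duplicate SD of 1.82 log2 units. Adjusted over the list alone COL7A1 passed the trend test, with 0 of 33 over all genes. Cholesterol synthesis genes had medians of 0.21, 0.51, 0.10 and 0.01, within the random range, but stood at -0.70 against the mixture at 48 h (percentile 0.27). MVD was 4.51-fold above 0 h at 48 h, SREBF2 5.81-fold above at 24 h with a duplicate SD of 1.70 log2 units, and SCD and SREBF1 3.2-fold and 4.23-fold below at 48 h. Second probes gave log2 changes of 0.42 for SREBF2 at 24 h and -0.32 for SCD at 48 h. The trend test passed 0 of 11, over all genes and adjusted over the list alone.

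Respiratory chain genes had medians of 0.13, 0.06, -0.08 and -0.16, within the random range, and 0.17 against the mixture at 6 h (percentile 97.6). NDUFB3, UQCRB, NDUFB1 and ATP5PO were 2.32-, 2.08-, 2.26- and 1.62-fold below 0 h at 48 h, and a second ATP5PO probe gave a log2 change of -0.01. Ribosomal protein genes had medians of -0.07, 0.15, -0.08 and -0.05. The value at 12 h lay above 9790 of 10000 intensity-matched random lists, but at percentile 84 of lists matched on the slide, and turned to -0.20 with median centring. Against the mixture the list stood at 0.04 at 12 h (percentile 60.2), and at -0.23 and -0.22 at 6 and 48 h (percentiles 0.07 and 0.645). The 0 h array already stood at -0.14 (percentile 0.85). RPL39 and RPL22 were 3.14-fold and 2.17-fold below, and RPL14 and RPS19 4.41-fold (no duplicate SD) and 2.33-fold above 0 h at 48 h. The trend test passed 0 of 44 respiratory chain and 0 of 57 ribosomal protein genes, over all genes and adjusted over the list alone.

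Several astrocyte and glioma genes were lower at 48 h, while the list median stayed within the random range at -0.01, -0.23, -0.05 and -0.25. Against the Ad-LacZ mixture it was -0.55 at 48 h, at percentile 0.16 of random lists. GFAP, the intermediate filament of astrocytes, was 116-fold below 0 h at 48 h (log2 -6.86 ± 0.14) and 6.25-fold at 24 h. The growth factor receptor PDGFRA was 11-fold and the fatty acid binding protein FABP7 8.06-fold below, and EGFR, another growth factor receptor, 12.3-fold above 0 h at 48 h. Neither PDGFRA nor EGFR had a signal in both duplicates of both the 0 and the 48 h array. Against the mixture EGFR stood at -3.59 on the 0 h array and 0.04 at 48 h, and GFAP at 2.84 and -4.02. Adjusted over the list alone 6 of 15 passed the trend test downward (GFAP, SOX9, VIM, FABP7, PDGFRA and PTPRZ1) and 1, EGFR, upward, with 0 over all genes.

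Markers of other cell types were measured in small numbers. Epithelial markers had medians of 0.15, 0.12, 0.61 and -0.17, with KRT18 2.89-fold above and KRT7 3.04-fold below 0 h at 48 h, CLDN4 6.22-fold below at 24 h and EPCAM 2.77-fold above at 24 h. The duplicate SDs of the last pair were 3.01 and 1.46 log2 units, about as large as their log2 changes of -2.64 and 1.47. Against the mixture they stood at 0.59 at 6 h and 0.79 at 24 h (percentiles 98.5 and 99.9). Neuron markers had medians of 0.21, 0.43, 0.16 and -0.60, with ENO2 1.99-fold, DCX 1.58-fold, MAP2 1.1-fold and NEFL 1.03-fold below 0 h at 48 h, and stood at -0.76 against the mixture at 48 h (percentile 1.61). Leukocyte markers had medians of -0.62, 1.30, -0.18 and 0.41, and at 12 h 5 of 8 were at least 2-fold higher, above 9822 of 10000 random lists, none of them 2-fold in both duplicates, and the median against the mixture was 0.65 (percentile 92.3). TYROBP was 7.41-fold and LCP1 4.34-fold below, and CD79B 1.73-fold and ITGAX 1.32-fold above 0 h at 48 h. Endothelial markers had medians of 0.30, 0.70, 0.33 and -0.36, with VWF 1.58-fold and ERG 1.29-fold below and FLT1 1.21-fold above 0 h at 48 h (duplicate SD 4.74 log2 units), and a second ERG probe gave a log2 change of 1.16. In the trend test 0 members of these 4 lists passed, over all genes and adjusted over the list alone. Of the 76 list medians over 19 lists and 4 times, 16 lay outside the central 95% of intensity-matched random lists. Outside that of slide-matched ones lay 14, and for genes drawn at random 3.8 are expected. The 4 times share the 0 h array, and genes of a list may move together on a single array. The excess therefore does not measure variation between cultures.

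Beyond the trend genes, those with the largest mean change over 24 and 48 h included NRARP, a regulator of Notch signalling, with a log2 change of 13.17 at 48 h, the immediate-early transcription factor EGR1 with 6.77 and the homeobox gene HOXB9 with 6.03. TEX11 stood at 6.49, KCNH2, a potassium channel, at 5.86, TUT1 at 5.52 and LCN12 at 5.48. TMEM143 stood at -11.21, the homeobox gene PKNOX1 at -7.74, WDR44 at -6.34, PSKH1 at -6.01, GALNT4 at -4.22 and ATPAF1 at -4.09. Of these and GFAP, 14 genes in all, 1 (GFAP) had a signal in both duplicates on the 0, 24 and 48 h arrays. Against the mixture TMEM143 stood at 11.25 on the 0 h array and 0.04 at 48 h, and WDR44 at 6.21 and -0.13. KCNH2 stood at -5.33 and 0.54, and HOXB9 at -5.13 and 0.90. The changes of these genes thus come mostly from the 0 h array. By contrast, NRARP stood at -3.71 and 9.46, and PKNOX1 at 2.58 and -5.16. At 48 h 1151 genes were at least 2-fold higher and 917 lower than at 0 h, of 7325 measured (28.2%). The 2-fold count at 48 h with the authors' matrix was 477 higher and 624 lower, of 4204 measured, where the median gene stood at -0.14. Both duplicates were 2-fold in the same direction for 943 genes. Of 5805 genes with both duplicates, 1308 were at least 2-fold in their mean, against 218 expected from duplicate noise alone. That noise was taken from the difference between the changes of the duplicates, so errors shared by both duplicates are not in it, here and at the other times. On slide 5 the counts were 69 against 41. Of 286 genes at least 2-fold on their brighter slide and measured on another, 211 (73.8%) moved the same way there.

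At 24 h EGR1 stood at a log2 change of 4.82, HOXB9 at 5.97, NRARP at 7.77 and LCN12 at 7.27. KCNH2 stood at 5.36, TUT1 at 4.94, TEX11 at 4.14, TMEM143 at -10.74, ATPAF1 at -6.09, WDR44 at -5.97, GALNT4 at -5.80, PSKH1 at -4.53 and PKNOX1 at -1.71. In all 1136 genes were at least 2-fold higher and 1017 lower, of 7664 measured. The 2-fold count at 24 h with the authors' matrix was 602 higher and 524 lower, of 4384 measured. Both duplicates were 2-fold for 821. Of 6058 genes with both duplicates, 1318 were at least 2-fold in their mean, against 334 expected from duplicate noise. The counts were 234 against 107 on slide 2 and 63 against 37 on slide 5. On another slide 206 of 308 genes (66.9%) moved the same way.

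At 12 h the highest changes were those of SPTLC1, a subunit of the first enzyme of sphingolipid synthesis, with a log2 change of 8.84, YBEY with 7.99, the kainate receptor subunit GRIK5 with 6.95, SNRPN with 6.51 and the inositol phosphatase INPP5D with 6.50. The lowest were TMEM143 at -12.47, IGFBPL1 at -8.94, the Cajal body protein COIL at -8.87, UGT3A2 at -8.72 and ZNF789 at -8.09. None of these had a signal in both duplicates on both arrays. Against the mixture TMEM143 stood at -1.22 and YBEY at -1.47 at 12 h, so their changes come mostly from the 0 h array. SPTLC1 stood at 8.44 and COIL at -9.50 at 12 h. In all 1101 genes were at least 2-fold higher and 1115 lower, of 7235 measured. The 2-fold count at 12 h with the authors' matrix was 706 of 3998 measured, 333 of them higher. Both duplicates were 2-fold for 765. Of 5552 genes with both duplicates, 1254 were at least 2-fold in their mean, against 341 expected from duplicate noise. On slide 5 the counts were 53 against 38. On another slide 145 of 245 genes (59.2%) moved the same way.

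At 6 h the highest changes were those of PCSK1N, an inhibitor of a prohormone convertase, with a log2 change of 9.12, YBEY and HPS4 with 8.60 each, YIPF4 with 6.58 and LCN12 with 6.22. The lowest were TMEM143 at -10.06, PCOTH at -8.88, the cation channel TRPV2 at -8.26, TIPRL at -7.63 and the small GTPase RAB30 at -7.26. None of these had a signal in both duplicates on both arrays, and with signals floored RAB30 stood at 0.29 at 6 h and SNRPN at -0.90 at 12 h. Against the mixture the 0 h array stood at 11.25 for TMEM143, -9.47 for YBEY, 7.66 for PCOTH and 7.23 for RAB30. It stood at -5.51 for HPS4, -5.16 for LCN12, 4.66 for TRPV2, 1.18 for PCSK1N, 0.60 for YIPF4 and 0.44 for TIPRL. In all 990 genes were at least 2-fold higher and 762 lower, of 7090 measured. The 2-fold count at 6 h with the authors' matrix was 195 higher and 158 lower, of 4121 measured. Both duplicates were 2-fold for 471. Of 5482 genes with both duplicates, 930 were at least 2-fold in their mean, against 300 expected from duplicate noise. On slide 5 the counts were 28 against 32. On another slide 100 of 188 genes (53.2%) moved the same way.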

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

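Chosen after seeing the data were the floored signals, slides 3 to 5, the second loess along the slide, slide-matched random lists and the condition on both duplicates; the other alternatives were planned. No paired analysis was possible because each time point has 1 array. With, in this order, the authors' matrix, genes above the median intensity, slides 3 to 5, a 3-fold threshold and both duplicates, the 2-fold count at 6 h became 353, 803, 599, 764 and 471. The 2-fold count at 12 h became 706, 1090, 763, 1076 and 765, the 2-fold count at 24 h 1126, 1120, 1023, 996 and 821, and the 2-fold count at 48 h 1101, 1190, 1032, 998 and 943. The stricter filter, the slides, the 3-fold threshold and both duplicates leave fewer genes by construction. For the matrix the cause was not tested. The other alternatives left these counts within 1.5 times.

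The trend count became 0 with median centring (562 genes at an unadjusted p under 0.05), 74 with the authors' matrix, 0 with floored signals (1069 unadjusted), 1 with hours in place of ranks, and 0 without an intensity trend in limma's variance (717 unadjusted). Leaving out the 0, 6, 12, 24 or 48 h array gave 0, 2, 1, 0 and 0, with 1 residual degree of freedom fewer in each fit; for the other settings the cause was not tested. With an offset of 50, no filter, the stricter filter, the mean over probes, the second loess, slides 3 to 5 and the logarithm of time it was 17, 16, 16, 11, 23, 21 and 15. The genes that passed kept their sign in each setting that measured them.

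The mitosis median at 48 h became -1.76 with median centring, -1.90 with the matrix, -0.66 with floored signals, -1.76 on slides 3 to 5 (6 genes) and -0.74 against the mixture. The pooled p53 median at 48 h became 1.49 with median centring and 1.73 on slides 3 to 5 (11 genes). Reversed were the ribosomal protein median at 12 h, -0.20 with median centring, and with floored signals RAB30 at 6 h, 0.29, and SNRPN at 12 h, -0.90; the cause was not tested. Of 789 list medians under alternatives 710 moved by less than the spread of random lists, 78 by more, and 1 that had stood outside the random range changed sign. Of 872 values of named genes, 425 kept their trend call or moved by less than the duplicate SD, 407 moved by more or had no duplicate SD, 38 lost their trend call and 2 reversed. Signal is the limit for the largest single changes: 0 of the 20 named at 6 and 12 h had both duplicates above 0 on both arrays.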

Other observations

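Gene families were compared by the stem of their symbols, a grouping made after seeing the data. Some families, such as RPL, RPS and COL, also have members in the lists. Integrin alpha genes (ITGA), receptors for the extracellular matrix, had a median log2 change over 24 and 48 h of 0.84, with 8 of 10 higher. Aldehyde dehydrogenases (ALDH) stood at 0.57, with 9 of 12 higher, and translation initiation factors (EIF) at 0.30, with 25 of 33 higher. Of 97 families, 5 lay outside the central 95% of random lists and 4.85 are expected by chance, so these families do not stand out as a group. Of 2178 spots with no single gene name, 0 passed limma's trend test and 171 reached an unadjusted p under 0.05, against 108.9 expected.

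The orders of the arrays were a planned test. The tests of the mitosis genes, of genes on several slides, of the Cy3 level and of the 0 h ratio were chosen after the result was seen, and pooling the p53 lists, matching random lists on the slide and 1 of the 4 scalings (the second loess) were chosen after seeing the data. For the p53 targets, higher at 48 h, the pooled median lay at percentile 100 of random lists from the same slides. Each slide of each array had already been centred in normalization. Level differences between slides were thus removed beforehand, and this test decides little about them. The choice among 4 scalings is argued against as the cause, since the lowest median over them was 1.19. Of the 4, the offset and the second loess keep the loess per slide, so median centring and the authors' matrix carry this test. Floored signals were not among them. Time after infection, shared by cells given LacZ virus, stays open: the 0 h ratio to the mixture was 0.134 (random -0.304 to 0.16), and the make-up of the mixture is unknown. An effect of the transduced p53 is therefore a hypothesis that these arrays could not separate from time after infection.

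For the mitosis genes, lower at 48 h, the choice among the same 4 scalings is argued against (highest median -1.1). Floored signals, where the fall was smaller, were not among them. Their median lay at percentile 0 of random lists from the same slides, which decides little about slide differences for the reason given above. Time after infection may contribute: the list stood at 0.241 over the mixture on the 0 h array, above the random range of -0.316 to 0.195, as it would if the LacZ cells had lower mitosis genes too. The median against the mixture was still -0.74 at 48 h. A part due to p53 stays open as well, since no LacZ sample matched in time was measured here.

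For genes at least 2-fold from 0 h, error of single spots or slides is argued against as the whole cause at 48 h, where 73.8% (exact binomial interval 68.3 to 78.8) of genes on several slides moved the same way. On slide 5 alone it stays open for a larger part. There 69 of 252 genes with both duplicates were at least 2-fold at 48 h, against 41 expected from duplicate noise. At 6 h the share was 53.2% (45.8 to 60.5), which is consistent with such error. Across genes, which are not independent replicates, Pearson's r between slides was 0.0567 at 6 h and 0.291 at 48 h (Spearman's rho 0.113 and 0.323). Whether the Cy3 level of a slide contributes stays open. The test used the median Cy3/Cy5 ratio and not Cy3 itself, and that ratio shifted by over 4-fold from 0 h in only 2 of 20 slide and time combinations, both on slide 1, with a median of 31.15% 2-fold genes against 27% (exact two-sided permutation p = 0.553). No biological explanation was tested for these counts.

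The trend count was set against all 60 orders of the 5 arrays, with an order and its reverse taken as 1. The real order gave 16 genes, the highest other order gave 0, and 1 of the 60 gave as many. A chance order is therefore argued against, though not excluded, for this count under the loess processing alone. Other orders were not run under other settings, and there the real order itself gave 0 genes with median centring, floored signals, no intensity trend in the variance, or without the 0, 24 or 48 h array.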
